A study of Homo sapiens with 8 samples.

How the data were processed

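RNA from MKN45 cells was profiled on 8 single-colour Agilent whole human genome arrays, 4 after JMJD2A siRNA and 4 after control siRNA, 24 h after transfection. Per the labels' protocols, RNA was extracted with a silica column kit and labelled with a cyanine 3 nucleotide by T4 ligase. The scanner files hold intensity values, and per the file headers Feature Extraction 10.7.1.1 subtracted the background and detrended the processed signal within each array; the submitters' processing notes give version 10.7.3.1. The processed signal was not normalized between arrays per the file headers. The authors also deposited a table of log2 values, whose scale and centring were found by comparison. All of its 42545 rows had a median within 0.001 of 0, and over 20100 probes well above background on all 8 arrays each column had a Pearson r of 0.998 to 0.999, across probes that are not independent replicates, and a slope of 0.997 to 0.999 against the row-centred log2 processed signal of the same array. The values were therefore log2 values centred on each probe's median, and the direction follows that of the signal. The exact scaling between arrays stays unknown. The column medians were -0.06, -0.01, -0.05 and -0.05 for JMJD2A siRNA replicates 1 to 4 and 0.13, -0.01, 0.11 and 0.08 for control siRNA replicates 1 to 4.

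Each array had 62976 spots, of which 58717 were not control spots and stood for 42405 probes. The main values were log2 of the processed signal minus the 75th percentile of it over the non-control spots of the array. Outlier-flagged spots (336 to 465 per array) were left out, and the spots of a probe were averaged. No spot was saturated, a count of 0. Probes well above background on at least 4 of the 8 arrays, whatever their group, were kept, which left 22833 probes, and 7 of these were left out because no unflagged spot remained on an array. The files hold no gene name column. Accessions were therefore matched without versions to a RefSeq gene table of assembly GRCh38.p14, used for names only because the files use hg19, and no coordinates are given. This named 25422 probes with 19483 gene symbols, and 16983 probes stayed unnamed, 8263 of them probes for long intergenic RNA regions. For a gene with several probes the one with the highest mean over all 8 arrays was tested, and 3081 genes had more than 1 probe to choose from. The 19181 features tested were 13289 genes, 2901 long intergenic RNA regions and 2991 other unnamed probes. Where genes that rose had other tested probes, 154 of 172 such probes went the same way and 69 of these passed the threshold, and for genes that fell 91 of 103 went the same way and 12 passed; none that passed the threshold went the opposite way.

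Differences are JMJD2A siRNA minus control siRNA, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not set them against other genes. The 29 lists were histone demethylases, H3K9 and H3K36 methyltransferases, 3M complex and partners, interferon-stimulated genes, G1/S cell cycle, G2/M cell cycle, p53 targets, DNA damage signalling and repair, fluoropyrimidine and platinum response, apoptosis regulators, gastric and intestinal epithelium, epithelial-mesenchymal transition, MYC targets, hypoxia and glycolysis, unfolded protein and integrated stress response, cholesterol and fatty acid synthesis, NF-kB and inflammatory cytokines, immediate early and AP-1, NRF2 and oxidative stress, Wnt targets, cytosolic ribosomal proteins, oxidative phosphorylation, heat shock and chaperones, replication-dependent histones, RNA interference machinery, fibroblast, leukocyte and endothelial markers, and zinc finger genes. The lists, tests, alternatives and rule for named genes were fixed before the data were examined. The rule named KDM4A; CCDC8, CUL7 and OBSL1, from published work on JMJD2A; the 12 largest rises and 12 largest falls among features with a gene symbol that passed the threshold, did not overlap between groups and were well above background on all 4 arrays of at least 1 group; and up to 4 members per list with the smallest adjusted p under 0.05, or up to 2 as values where a list had none. Some genes that the rule names are not reported here. A probe not well above background on any array of a group was given a bound there. The bound sets the mean of the brighter group against the mean, per array of the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background.

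The alternatives were quantile normalization, scaling to the median, normexp background correction with an offset of 50, the deposited log2 table, no filter on dim probes, a filter requiring all 8 arrays, keeping outlier-flagged spots, the mean of a gene's probes, every probe on its own, an intensity trend with robust variance, the replicate number as a block, array weights, a threshold of 0.01, and leaving out each array in turn. Normexp used the median spot signal because the files hold no mean signal. A single slide and a single scan left no batch to fit as a block. On simulated data with 200 of 19181 features changed, the JMJD2A siRNA against control siRNA fit recovered 57 of 100 changes of 0.5 and 88 of 100 changes of 1 on the log2 scale, with 7 false calls among 152. In the same simulation, whose genes varied independently of one another, camera called the 1 shifted list and 0 of 28 unshifted lists.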

Results

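Gene expression was measured in MKN45, an established gastric cancer cell line, 24 h after transfection with an siRNA against JMJD2A or with a control siRNA. JMJD2A, whose current gene symbol is KDM4A, is a demethylase of histone H3 lysines 9 and 36. Each group had 4 arrays, and all 8 arrays lay on 1 slide and came from 1 scan. The 4 JMJD2A siRNA arrays lay in row 1 of the slide and the 4 control siRNA arrays in row 2, so slide row and group cannot be told apart. The 75th percentile of processed signal was between 1314 and 1510 intensity units with JMJD2A siRNA and between 1108 and 1610 with control siRNA. The share of probes well above background was 56.3% ± 2.05 (SD, n = 4) with JMJD2A siRNA and 51.5% ± 2.42 (SD, n = 4) with control siRNA. The number of arrays limits the precision, and since the labels do not say whether replicates were separate cultures, the p-values describe the spread between these samples.

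The first comparison asked whether the siRNA lowered its target. KDM4A signal was 5.70-fold lower with JMJD2A siRNA than with control siRNA (95% confidence interval 5.00 to 6.49). The normalized log2 signal of its only probe, A_33_P3420655, was -2.76 ± 0.147 with JMJD2A siRNA and -0.25 ± 0.0769 with control siRNA (SD, n = 4 each). The log2 difference of KDM4A was -2.51 with a standard error of 0.0827 and a limma adjusted p of 3.71e-06. The two-sided exact permutation p of the KDM4A probe was 0.02857, the smallest that 4 against 4 arrays can give. The probe was well above background on all 8 arrays.

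The second comparison asked which transcripts differed after JMJD2A silencing, the purpose that the series title states. Of 19181 features tested, 877 rose and 497 fell with JMJD2A siRNA at a limma adjusted p under 0.05. Most changes were small, with a median absolute log2 difference of 0.42 among the 1374 changed features. Changes of at least 2-fold comprised 53 rises and 7 falls, against 27 and 3 with normexp background correction, 59 and 18 with array weights, and 84 and 739 with no filter on dim probes. Changed features well above background on all 8 arrays split into 744 rises and 479 falls. Those well above background on 4 to 7 arrays split into 133 and 18. The lowest normalized log2 signal well above background averaged -5.82 with JMJD2A siRNA and -5.12 with control siRNA, so the filter can favour rises. Among features that carry a gene symbol, 695 rose and 364 fell, and among long intergenic RNA regions 95 rose and 78 fell. Rises were 63.8% of the changed features, against 74.3% with scaling to each array's median (1135 rises and 392 falls) and 49.2% with normexp background correction (699 rises and 722 falls). In 1368 of the 1374 changed features the 4 JMJD2A siRNA values did not overlap the 4 control values, a separation that 17.4% of all tested features showed and chance gives in 2.86%. The total was 663, 619 and 608 without JMJD2A siRNA replicate 1, 2 and 3 in turn, 2652 with array weights, and 8356 with no filter on dim probes.

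Among the falls, CKAP5 stood beside KDM4A. CKAP5, a microtubule polymerase of the mitotic spindle, fell by 2.23 on the log2 scale (standard error 0.0596, limma adjusted p = 1.93e-06), from 2.02 ± 0.0885 to -0.21 ± 0.0341 (SD, n = 4 each). SCAPER, a protein that binds cyclin A at the endoplasmic reticulum, fell by 1.35, and RSC1A1, a regulator of a sodium-glucose transporter, fell by 1.20. RSC1A1 overlaps DDI2 in the reference annotation, and the DDI2 probe, which was not tested, was well above background on 3 control arrays and no JMJD2A siRNA array and was at least 2.34-fold lower with JMJD2A siRNA. The transcription factors LEF1 and ONECUT2 fell by 0.90 and 0.88, and the collagen gene COL12A1 fell by 0.90. EID2B, PGM2L1, CCDC158, DDX43 and SPRYD4 completed the 12 named falls, with log2 differences of -0.95, -0.92, -0.88, -0.85 and -0.83. The CCDC158 fall did not pass the threshold without JMJD2A siRNA replicate 2 (adjusted p = 0.0547).

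SAR1B, a GTPase of COPII vesicles, rose by 1.67 on the log2 scale (standard error 0.0749, limma adjusted p = 1.64e-05), and SCAMP1, a secretory carrier membrane protein, rose by 1.57. RAB14, a GTPase of endosomal transport, was not well above background with control siRNA and was at least 2.43-fold higher with JMJD2A siRNA (adjusted p = 0.000163). CHPF, which takes part in chondroitin sulfate synthesis, rose by 1.52 (standard error 0.0616, adjusted p = 1.25e-05). The kinase HIPK3, the focal adhesion protein TLN1, the pantothenate kinase PANK3 and the tRNA guanylyltransferase THG1L rose by 1.65, 1.63, 1.54 and 1.48, with HIPK3 well above background on 3 of the 4 control arrays. CHRM1, a muscarinic receptor, and PDE1B, a phosphodiesterase, were not well above background with control siRNA and were at least 1.65-fold and at least 1.70-fold higher (adjusted p = 0.012 and 0.0018). The CHRM1 rise did not pass the threshold with normexp background correction (adjusted p = 0.0608), and 1 JMJD2A siRNA array stood apart from the other 3 for this gene.

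**Figure D1:**
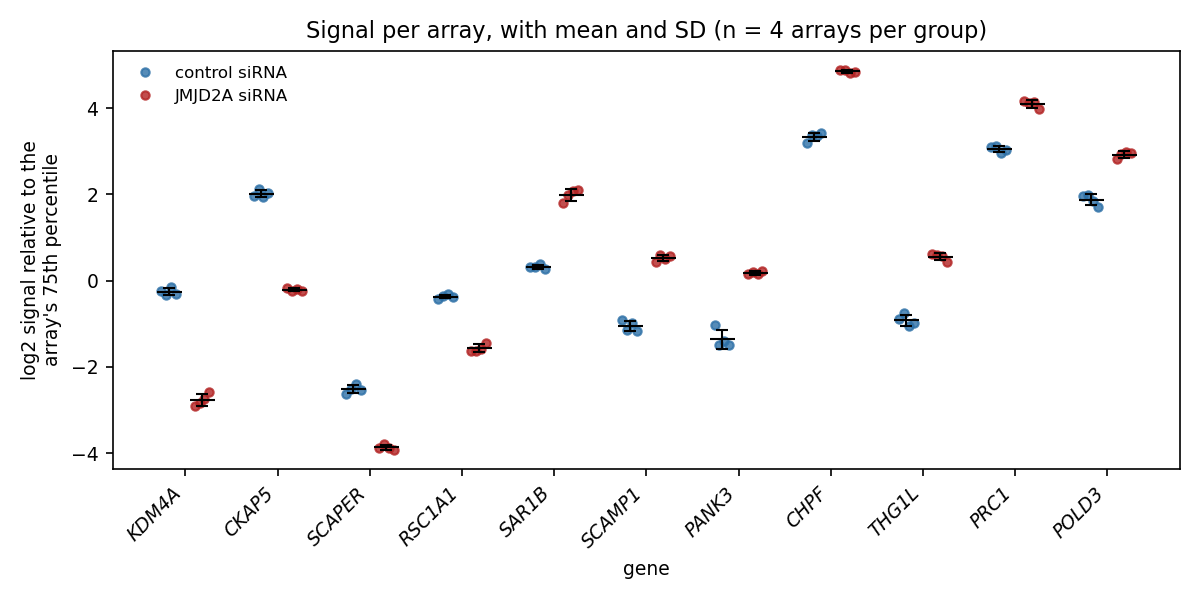
Normalized log2 signal of 11 genes on each array (points), with the group mean and SD (bars), for control siRNA (blue) and JMJD2A siRNA (red), 4 arrays each. The genes were chosen from the named genes after their values were seen, and in each the 4 values of a group lie apart from the 4 of the other group.

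**Figure D2:**
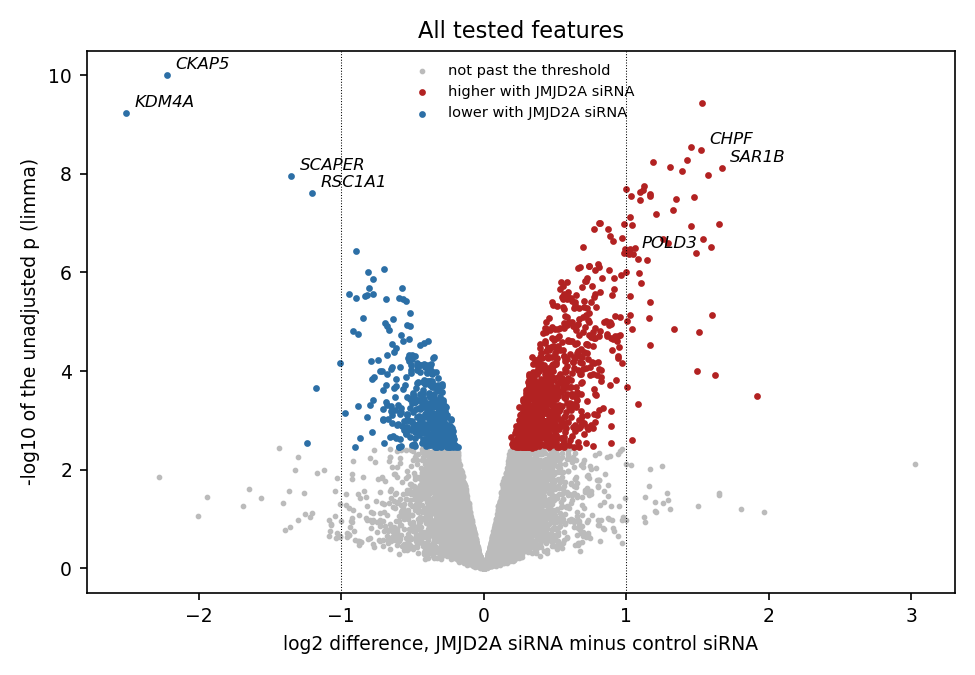
Log2 difference, JMJD2A siRNA minus control siRNA, against -log10 of the unadjusted limma p for 19181 features. Red points (877) rose and blue points (497) fell at an adjusted p under 0.05, dotted lines mark 2-fold, and 53 rises against 7 falls lie beyond them.

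CCDC8, a subunit of the 3M complex that published work on JMJD2A in gastric cancer concerns, was not well above background on any JMJD2A siRNA array. Of its 2 probes, A_33_P3402020 was well above background on 1 control array. Its normalized log2 signal was -7.91 ± 0.274 with JMJD2A siRNA and -4.98 ± 1.20 with control siRNA (SD, n = 4 each). The bound from these values was at least 1.79-fold lower CCDC8 with JMJD2A siRNA, but it rests on control siRNA replicate 2, without which neither group had a measured level and no bound can be given. The other probe, A_23_P164958, was well above background on no array. Its 3M partners CUL7 and OBSL1 differed by 0.16 (standard error 0.0854, limma adjusted p = 0.303) and 0.04 (standard error 0.0584, adjusted p = 0.746). None of the 8 tested members of the 3M list passed the test over all features, and 2 of them, CUL9 and ANKRA2, were lower when adjusted over the list alone, with log2 differences of -0.25 and -0.20.

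Gene lists fixed before the data were examined described the response by theme. Of all 13289 tested genes with a symbol 1059 changed, and the count of changed members in a list was not tested against that share. Of 29 lists, 1 passed limma's camera test with a preset correlation, 5 had an unadjusted camera p under 0.05, and none passed with an estimated correlation. The list that passed was the G1/S cell cycle list, which was lower with JMJD2A siRNA (adjusted p = 0.000574). With an estimated correlation this list had an adjusted p of 0.353, and with fry 0.005996. Of its 46 tested members 35 had a negative log2 difference, and the list median was -0.11. Over all features EXO1, CCNE2 and UNG fell by 0.35, 0.43 and 0.24, whereas POLD3, a subunit of DNA polymerase delta, rose by 1.05; adjusted over the list alone, 11 members were lower and 1 was higher. In other groupings of the same 8 arrays a list with as small a camera p was common, so the camera call did not stand apart from chance.

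Among G2/M cell cycle genes, 4 of 48 rose and none fell over all features, and adjusted over the list alone 4 were higher and 1 was lower. The risers were PRC1, a bundler of spindle microtubules, by 1.04, the kinesins KIF11 and KIF20A by 0.64 and 0.62, and PLK1 by 0.56. The median of this list was -0.03 and its mean 0.01, and camera gave an adjusted p of 0.564. Of 40 p53 targets, 2 rose and 5 fell over all features, with the same counts adjusted over the list alone. E2F7, PLK2 and FAS fell by 0.47, 0.31 and 0.22, and TP53INP1 rose by 0.60 (camera adjusted p = 0.402). Of 48 genes of DNA damage signalling and repair (camera adjusted p = 0.149), FANCC rose by 0.38. CHEK1, REV1 and RNF168 fell by 0.28, 0.23 and 0.31. Adjusted over the list alone, 2 were higher and 6 lower, and the list passed camera without control siRNA replicate 3.

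Of 25 genes of fluoropyrimidine and platinum response, 3 changed, and the same 2 higher and 1 lower counts held adjusted over the list alone (camera adjusted p = 0.952). UCK1, a uridine-cytidine kinase, rose by 0.77, the copper transporter ATP7B rose by 0.24, and ABCC2, an efflux transporter, fell by 0.60. ABCC2 was also the 1 of 32 tested genes of the NRF2 list that changed. Of 38 apoptosis regulators, HTRA2 rose by 0.25 and 2 fell, FAS among them (camera adjusted p = 0.402); adjusted over the list alone, 2 were higher and 4 lower.

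Of 35 genes of gastric and intestinal epithelium, TFF3, PSCA and MUC1 rose by 0.31, 0.34 and 0.33 and none fell, and adjusted over the list alone 5 were higher. This list did not pass camera (adjusted p = 0.0537), but it passed under 5 of 12 other settings (adjusted p from 0.00013 to 0.114) and without JMJD2A siRNA replicate 3 (adjusted p = 0.0419). With an estimated correlation its adjusted p was 0.784, and with fry 0.0178. Of 37 hypoxia and glycolysis genes, 5 rose and none fell, and adjusted over the list alone 6 were higher. ANGPTL4 rose by 0.62, NDRG1 by 0.57, DDIT4 by 0.43 and HK1 by 0.36. Camera gave this list an adjusted p of 0.0525, and it passed under 5 of 12 other settings (adjusted p from 6.72e-05 to 0.0949) and in 4 of 8 fits with 1 array left out (JMJD2A siRNA replicates 1 and 3, control siRNA replicates 1 and 2; adjusted p from 0.0238 to 0.0811). With an estimated correlation its adjusted p was 0.353, and with fry 7.45e-06. For both lists 1 of the 5 settings passed was no filter on dim probes. That setting also sets a list against features well above background on no array, whose median difference was -0.70. Of 20 tested genes of epithelial-mesenchymal transition, CCN1 and THBS1 fell by 0.38 and 0.43, and adjusted over the list alone 2 were higher and 2 lower (camera adjusted p = 0.903).

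Members of the signalling lists went both ways. Of 21 Wnt targets, APCDD1, EPHB2 and EPHB3 rose by 0.49, 0.53 and 0.36, and 3 fell, LEF1 among them; adjusted over the list alone, 5 were higher and 5 lower (camera adjusted p = 0.911). Of 34 immediate early and AP-1 genes, DUSP5 and PHLDA1 rose by 0.88 and 0.32, and SPRED1 and MYC fell by 0.23 and 0.26; adjusted over the list alone, 4 were higher and 2 lower (camera adjusted p = 0.911). Of 23 NF-kB and cytokine genes, PLAUR rose by 0.45, and CXCL1 and CXCL3 fell by 0.54 and 0.36; adjusted over the list alone, 1 was higher and 3 lower (camera adjusted p = 0.402). Of the 14 genes of the RNA interference machinery, 3 rose and 3 fell. AGO4, well above background on only 1 of the 4 control arrays, rose by 1.59, TNRC6A by 0.97 and TARBP2 by 0.47, and XPO5 fell by 0.37; adjusted over the list alone, 4 were higher and 3 lower (camera adjusted p = 0.952, list median -0.06 and mean 0.14).

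**Figure D3:**
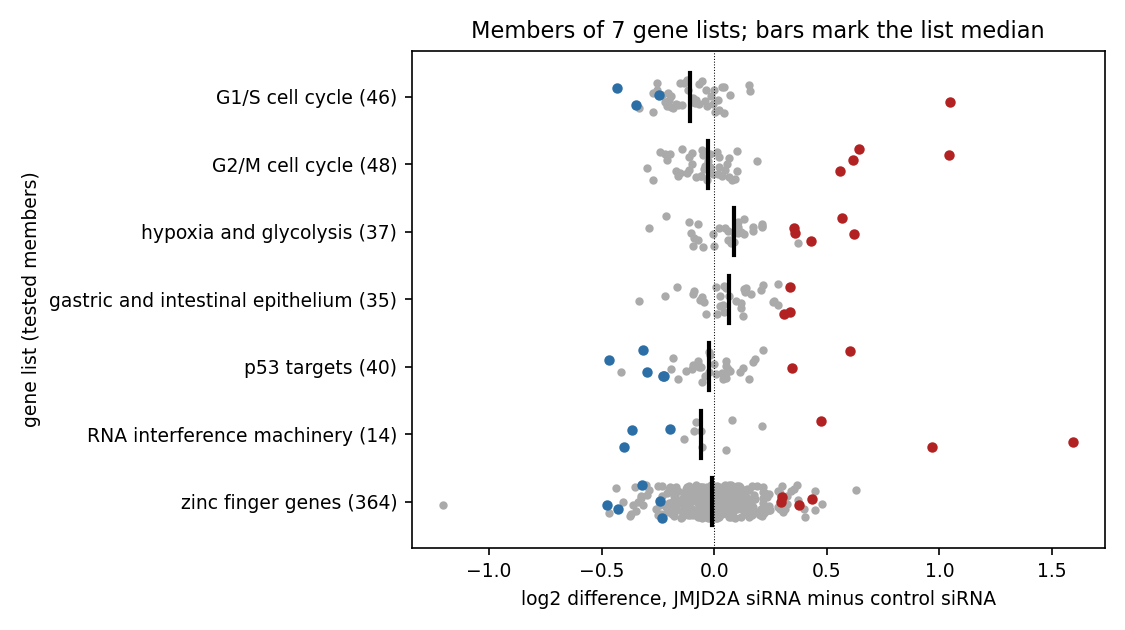
Log2 difference, JMJD2A siRNA minus control siRNA, for each tested member of 7 gene lists (points), with red and blue points for members that rose and fell at an adjusted p under 0.05, grey points for the others, and bars at the list medians. The G1/S cell cycle list has a median of -0.11, and POLD3 lies apart from it at 1.05.

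Few chromatin genes changed, but most genes did not change either: 1059 of all 13289 tested genes with a symbol did. Whether the count in any chromatin list differs from that share was not tested. Of 22 other histone demethylases tested, KDM6B rose by 0.37 (limma adjusted p = 0.0392) and none fell, and no member passed when adjusted over the list alone. None of 19 genes of the H3K9 and H3K36 methyltransferase list changed, and its members NSD2 and PRDM2 differed by -0.19 and -0.15 (adjusted p = 0.0975 and 0.102). Of the 19, 13 had a negative log2 difference, and the list was lower by fry (adjusted p = 0.0282) but not by camera (adjusted p = 0.402). The list also holds CBX1, CBX3, CBX5, TRIM28 and UHRF1, which are not methyltransferases. UHRF1, also in the G1/S list, had the most negative difference, -0.33, so the fry result is not one about methyltransferases alone. Of 364 zinc finger genes, 4 rose, ZNF12 by 0.43 and ZNF217 by 0.30 among them, and 5 fell, ZNF805 by 0.47 and ZNF93 by 0.43 among them; adjusted over the list alone, 2 were higher and 3 lower (camera adjusted p = 0.901). None of 33 replication-dependent histone genes changed (camera adjusted p = 0.236), although the list passed camera without control siRNA replicate 2.

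Stress, growth and innate immune lists held few changes, and their counts were likewise not tested against the share among all genes. OASL rose by 0.44 as the 1 of 35 interferon-stimulated genes that changed. INSIG1, a sterol sensor, fell by 0.52 as the 1 of 34 genes of cholesterol and fatty acid synthesis. CHORDC1, an HSP90 cochaperone, fell by 0.80 as the 1 of 23 heat shock and chaperone genes, with 3 lower adjusted over the list alone. The heat shock and chaperone list was lower by fry (adjusted p = 0.00204) but not by camera (adjusted p = 0.402). None of 40 MYC targets, 36 genes of the unfolded protein and integrated stress response, 66 cytosolic ribosomal protein genes and 37 oxidative phosphorylation genes changed over all features or adjusted over the list alone. The cytosolic ribosomal protein list passed camera without control siRNA replicate 2. Among markers of other cell types, COL5A1 rose by 0.58 and LUM fell by 0.65 of 6 tested fibroblast markers, and none of 7 leukocyte and 2 endothelial markers changed. Of the 76 changed genes that the rule for named genes takes in, 38 kept the call under all other settings and 50 with each array left out in turn. Without JMJD2A siRNA replicate 1, 2 or 3, 23, 25 and 24 of them lost it. FAS, REV1, RNF168 and MYC did not pass with scaling to the median, and CHRM1, KDM6B, RNF168, ATP7B, SPRED1, MYC, EPHB2 and EPHB3 did not pass with normexp background correction. Other tested probes of CCNE2, COL12A1, E2F7, FAS, XPO5 and ZNF217 went the same way, but none passed the threshold. For CHORDC1, CXCL1, EPHB2, MUC1, PANK3, PLK1, SCAMP1 and TFF3 at least 1 other probe passed.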

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

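The tests of the total count against other splits, of slide row, of single probes, of siRNA sequence, of the floor, and of the G1/S list and the smallest list p against other splits were chosen only after the results they concern were seen.

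For 10 genes a single JMJD2A siRNA array lay far from the other 3, by the ratio of its gap to the range of the group. The ratios were 0.9199 for CHRM1, 0.8291 for RNF168, 0.9365 for MUC1, 0.8637 for MYC, 0.8579 for APCDD1, 0.9158 for EPHB3, 0.8301 for PRDM2, 0.8717 for HYOU1, 0.9258 for H3C2 and 0.8671 for CDH5. Of 202 groups of 4 values examined, 10 were picked out, and about 10.1 are expected by chance. All 10 were groups of JMJD2A siRNA values and none were control siRNA values, an imbalance that was not tested. Among probes left out of the tests, 404 were well above background on 3 JMJD2A siRNA arrays and no control array, and 3 showed the reverse. Detection itself differed between the groups: the lowest normalized log2 signal well above background averaged -5.82 with JMJD2A siRNA and -5.12 with control siRNA, and the SD of negative controls was 3.28 to 5.12 against 6.67 to 8.47 intensity units. The filter on dim probes therefore admitted features that were dim with control siRNA more easily than the reverse.

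Without the filter on dim probes 7162 features were lower with JMJD2A siRNA and 1194 were higher. Of the falls, 6477 came from features well above background on no array. Probes well above background on no array had a median difference of -0.69794, so a lower floor of dim signal in the JMJD2A siRNA arrays is a candidate explanation. The 25th percentile of normalized log2 signal was -7.70 ± 0.20 with JMJD2A siRNA and -7.06 ± 0.284 with control siRNA (SD, n = 4 each), and the 2 dimmest spike-in transcripts shifted by -0.79 and -0.65. Slide row is confounded with group, so what lowered the floor stays open, and no biological explanation was tested.

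Rises of at least 2-fold outnumbered falls by 53 to 7. Under 4 scaling and background alternatives the smallest ratio of rises to falls was 6.375, and with array weights it was 3.28. Those 4 alternatives left the median difference of all features between -0.02 and 0.03. They could hardly turn an excess at 2-fold, so they cannot decide on scaling. Among features well above background on all 8 arrays the ratio was 6.3333 (38 rises and 6 falls). This argues against dim probes as the only cause. With no filter on dim probes falls were more frequent, 739 against 84 rises. Of 11 other probes of risen genes, 10 went the same way and passed the threshold themselves, which argues against single-probe signal for the 10 genes that had another probe. Loss of JMJD2A and other effects of the siRNA sequences cannot be told apart, because 0 arrays carried a second siRNA or untransfected cells. The same holds for the fall of CKAP5, which was near that of KDM4A in size.

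Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave 1374 changed features, and the highest of the others gave 0. The same held for changes of at least 2-fold, with 60 in the real split, matched by 1 split, and 0 as the highest other. The other splits mix the groups, so the group difference widens their spread and lowers their counts. A match by 1 of 35 splits is the smallest result this test can give. It argues against a chance split of these arrays but does not exclude it. Slide row and replicates that shared a culture are not addressed by it. For the 1223 changed features well above background on all 8 arrays, the median absolute change was 0.40. The largest shift of a spike-in with the same detection was 0.09049. Scaling each array to a percentile of its own signal removes a uniform shift beforehand. These features were also picked for having changed, and they went both ways. Setting their change against the spike-in shift therefore cannot decide whether slide row affected them. For the other 151 (133 higher and 18 lower, against 744 and 479), well above background on 4 to 7 arrays, 0 spike-ins had that detection. An array-wide effect of slide row on these features therefore cannot be told apart from the group. The spike-in well above background on 2 arrays shifted by 0.03. The 2 dimmest shifted by -0.79 and -0.65, the opposite way to most of the 151. A row effect, on particular transcripts or more widely, and an siRNA effect remain open.

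Chance was not excluded for gene lists: 32 of 35 splits gave at least the 1 list of the real split, with 5 as the highest other. The G1/S cell cycle list taken alone had its smallest camera p, 1.98e-05, in the real split, matched by 1 of 35 splits, with 0.000192 as the nearest other. That list was singled out because it had the smallest p of the 29 lists, so this count leaves out the choice. With the choice included, 19 of 35 splits had some list with a camera p as small, the smallest of them 8.60e-14, and chance was not excluded.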

How the results depend on the processing

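The fall of KDM4A kept its direction and passed the threshold under 12 other settings, with log2 differences from -2.56 to -2.10, and with each array left out, from -2.57 to -2.46. Where a count below moved, the cause was not tested unless stated. With no filter on dim probes 36453 features were tested, 8356 changed, 7162 were lower, 84 were at least 2-fold higher and 739 at least 2-fold lower (823 together), 4 lists passed, and the zinc finger list passed in the opposite direction (adjusted p = 0.005293). Without that filter the lists were also set against features well above background on no array, whose median difference was -0.70. With normexp 27 features were at least 2-fold higher and 3 lower (30 together). With array weights 2652 changed, 1411 higher and 1241 lower, 18 of them at least 2-fold lower. A threshold of 0.01 left 474 by construction. Lists past the test numbered 3 with median scaling, with normexp, with all 8 arrays required and with the mean of a gene's probes (in each the G1/S, gastric and intestinal epithelium, and hypoxia and glycolysis lists), 5 with fry and 0 with an estimated correlation. The G1/S list had adjusted p from 0.000481 to 0.406 over its settings, the highest with no filter.

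The replicate numbers did not pair the samples: correlations of deviations were -0.107, 0.101, 0.0526 and -0.0207 for replicates 1 to 4, and 2 of 4 correlated best with their own number. With the replicate block 424 features changed, 334 higher and 90 lower, 415 of them among the 1374. With each array left out in turn, 608 to 2010 features changed, 450 to 1082 higher and 150 to 928 lower, 50 to 61 were at least 2-fold higher and 5 to 11 at least 2-fold lower, and 1 to 4 lists passed. Fewer arrays also mean less power. The total was 663, 619 and 608 without JMJD2A siRNA replicate 1, 2 and 3. Falls numbered 173, 169, 150 and 318 without JMJD2A siRNA replicates 1 to 4, and 310, 928 and 259 without control siRNA replicates 1, 2 and 3, and falls of at least 2-fold 11 without control siRNA replicate 4. Of 1146 values of named genes under other settings, 1064 stayed on their side of the threshold, 60 lost it, 37 of them with the replicate block, and 22 gained it; with 1 array left out 643 of 768 stayed, 120 lost it and 5 gained it, and none reversed among named genes. No slide or scan block was run, since there was 1 slide and 1 scan. Signal over background limits dim probes, CCDC8 among them.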

Other observations

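All tests in this part were chosen after the results were seen, by testing 170 families of gene symbols in both directions with Fisher's exact test.

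Keratin genes were more frequent among the rises than other named genes. Of 27 tested, 9 rose (33.3% against 5.23% of named genes), with an adjusted p of 0.001891. KRT16, KRT6A and KRT14 rose by 1.17, 1.02 and 0.92, KRT17, KRT6C, KRT15 and KRT6B by 0.86, 0.67, 0.59 and 0.46, and the pseudogenes KRT16P2 and KRT19P2 by 1.04 and 0.40, whereas KRT80 fell by 0.43. KRT16 was well above background on only 2 of the 4 control arrays. KRT18 and KRT19, keratins of simple epithelia, differed by 0.01 and 0.14 and did not pass the threshold. Under 4 other scalings or backgrounds 9 or 10 keratins rose and 1 fell. A keratin response to JMJD2A siRNA may be a hypothesis to follow up, but several of these genes are close paralogs whose probes could share target RNA, which was not tested.

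Genes whose symbol is RAB followed by a number (11 of 64 higher, adjusted p = 0.05052) and syntaxin genes (4 of 14 lower, adjusted p = 0.05052) did not pass the correction. The former also hold genes that are not RAB GTPases, and RAB11FIP1 was such a gene among the rises. Of the risen genes, RAB14, RAB37 and RAB42 were well above background on no control array.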
